A study of Mus musculus with 24 samples.

How the data were processed

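The deposited table held 17545 genes by 24 libraries of signal: values that the authors, per the submitters' processing notes, had obtained with DESeq2 from gene counts. Those notes name FastQC 0.11.7, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19, HTSeq 0.6.1 and the build GRCm38, with the annotation not given in the sources used here. The values themselves showed that each library was its read counts divided by 1 size factor, since 100% of values were whole multiples of the smallest value of their column within a tolerance of 0.001. Dividing by that step recovered whole reads, 6422883 to 10856721 per library, for the count-based alternatives. The libraries were QuantSeq 3′ FWD, read from the 3′ end, so levels were not divided by transcript length. Gene symbols were matched to GENCODE M21 (17473 found, 99.6%, and 72 not found). No library was left out, and none of the 12 pairs of clones was a duplicate (chi-square per gene 26 to 155.7).

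Values were transformed as log2(normalized count + 1), and genes with at least 10 normalized counts in at least 2 libraries were tested (16158). The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend and robust) with 12 group means over all 24 libraries and 12 residual degrees of freedom, Benjamini-Hochberg over all genes of a comparison, and adjusted p under 0.05. Every adjusted p in the text is from limma unless another tool is named. With 2 clones per group the smallest exact permutation p is 0.33, so the test borrows its spread from all groups and assumes that they vary alike. These choices were made before the data were examined. Median SE was 0.55 for differences between groups and 0.78 for interactions.

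The 29 gene lists were written beforehand from general knowledge: naive pluripotency, general pluripotency, formative and primed pluripotency, neural progenitor, neuron, glia, mesoderm, endoderm, trophectoderm, 2-cell-like state, feeder fibroblast, Hox genes, developmental regulators with bivalent promoters in ES cells other than Hox, mitosis, G1-S and replication, p53 targets, imprinted genes, germline genes, Y-linked genes and Xist, ATF4 and unfolded protein stress, cholesterol synthesis, hypoxia and glycolysis, mitochondrially encoded transcripts, Wnt targets, Nodal and TGF-beta targets, BMP targets, FGF-ERK targets, retinoic acid targets, and the UTF1 and Cdc14 family. They were tested with limma camera at a preset inter-gene correlation of 0.01, lists of at least 3 measured members, adjusted over the lists of a comparison. The alternative estimated the correlation of each list from the data, and its adjusted p is printed wherever it lost the call. A list median with bounded genes sets a gene to 3 reads per library in a group where neither clone had a read. It is printed where it moved the median.

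Genes were named by rule. Cdc14a, Cdc14b and Utf1 were given in every group. In each comparison the 10 highest and 10 lowest genes by fitted log2 fold change were ranked among those called whose libraries did not overlap between groups (for interactions, whose clone responses did not overlap) and whose mean was at least 20 normalized counts, leaving out predicted genes, pseudogenes, Y-linked genes and Xist. Up to 4 members with the smallest adjusted p were added for each list described, and fewer were printed where space was short.

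Choices were varied as follows: pseudocounts of 0.25 and 5, no filter, a filter of 50 normalized counts, TMM factors, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a fit with only the groups compared, clone as a random effect, a replicate block, leaving out each library in turn, and the estimated correlation. Left out one at a time, a library leaves a lone clone in its group, and that clone is assumed to vary like the clones of other groups. Clones of the same genotype and number are the same line across days, so they were paired for changes over days and for interactions. Their deviations from group means correlated at -0.115 to 0.248 across days, a weak sharing. Between genotypes the labels share only the number. Added after the data were seen were a fit without the 3 libraries with over 7% of reads on Gm42418, a crossed block and the alternatives for the correlations of knockout effects. The common response was measured over genes with adjusted p under 0.05 and an absolute log2 change of at least 1 for the day averaged over Cdc14a KO and Cdc14b KO, in a limma fit of their 12 libraries alone. Its measure was the median change signed by their direction there. Overlap of knockout effects was compared with 100 simulations without an effect but with shared controls. Components came from log2 values, and figures from Python 3.11.15 with matplotlib 3.10.9.

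The procedure was tested on simulated data for Cdc14ab KO against wild type at day 7, with 200 changed genes in each of 5 simulations. limma found 1.2%, 37% and 78.2% of genes changed 2-, 4- and 8-fold with 6.2 false calls, edgeR 1.2%, 32.2% and 76.4% with 2.8, and DESeq2 8.1%, 57.9% and 88.2% with 23.8. A list of 28 genes with 14 lowered 4-fold was called in 5 of 5 simulations, and 0 of 100 unchanged lists were called. Genes were simulated as independent, so these results do not cover false calls of lists whose members vary together. A 2-fold change of a single gene was mostly missed, and limma and edgeR missed a 4-fold change more often than they found it. A count of 0 does not exclude such changes. Interactions, which have a larger SE, were not simulated.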

Results

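Mouse embryonic stem cells derived from blastocysts were profiled at days 0, 2 and 7 of neural differentiation, in wild type and in lines lacking Cdc14a, Cdc14b or both genes (Cdc14ab KO). Cdc14a and Cdc14b encode dual-specificity phosphatases that remove phosphates placed by cyclin-dependent kinases, and the series names UTF1, a chromatin factor of pluripotent cells that binds bivalent promoters, as their link to differentiation. Each genotype had 2 clones, numbered 1 and 3, sampled at each day, which gave 24 libraries in 12 groups of 2. Day 0 cells were kept with LIF, and the differentiating cells were moved to N2B27 medium with EGF and FGF2, which were withdrawn at day 6. Libraries held reads from the 3′ ends of polyadenylated transcripts over 17545 listed genes. Reads per library ranged from 6422883 (wild-type day 7 clone 1) to 10856721 (Cdc14ab KO day 2 clone 3), with a median of 8015247. Levels are given as normalized counts, mean ± SD of 2 clones, and changes as log2 fold change ± SE with n = 2 clones per group. The p-values measure the spread between these clones, while lower bounds set at 3 reads per library cover counting error only, from reads without molecular identifiers.

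The day of differentiation separated the libraries along the first principal component (28.3% of the variance). Day 0 libraries lay between -95.44 and -41.38, day 2 libraries between -21.61 and 6.02, and day 7 libraries between 41.86 and 92.15. On the second component (14.3%), the day 7 libraries of Cdc14b KO (79.34 and 12.07) and Cdc14ab KO (60.05 and 41.8) lay above those of wild type (-8.81 and -43.55) and Cdc14a KO (-20.96 and -33.49). Clones of 1 group correlated at 0.894 to 0.96. Cdc14ab KO day 0 clone 1 stood apart: its mean correlation with the other day 0 libraries was 0.887, 5.23% of genes were at 0, and 8.7% of its reads fell on Gm42418, a transcript that overlaps ribosomal RNA. Gm42418 also took 10.77% of the reads of Cdc14a KO day 2 clone 1 and 7.97% of Cdc14b KO day 0 clone 3.

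**Figure D1:**
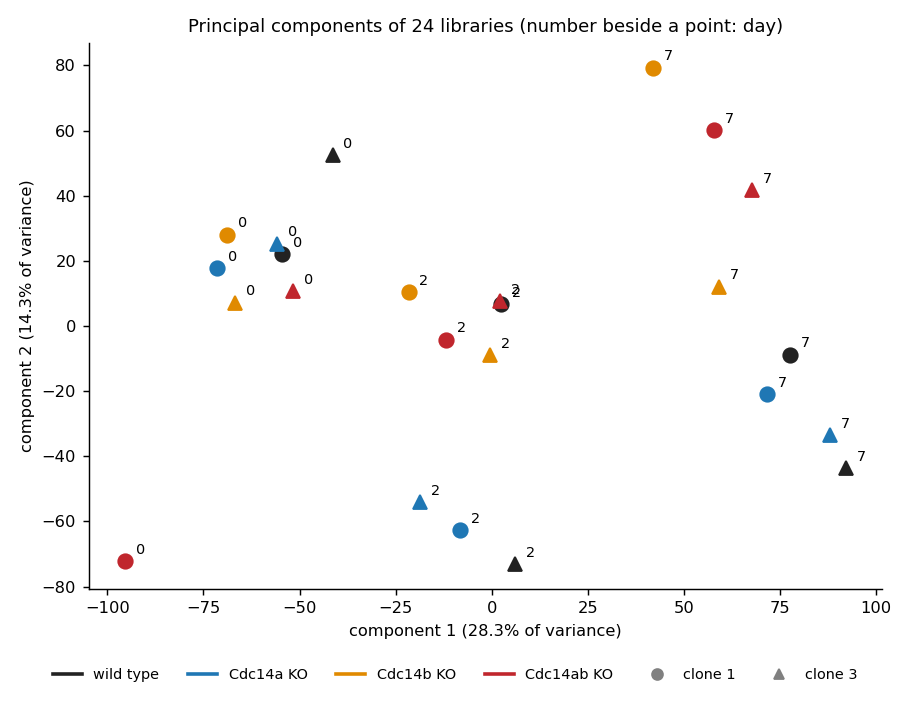
Each point is 1 library placed on the first (28.3% of variance) and second (14.3%) principal components of log2 normalized counts, coloured by genotype, shaped by clone and numbered by day. Day 0 libraries end at -41.38 on the first axis and day 7 libraries start at 41.86.

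Levels of sex-chromosome transcripts varied between the lines, in part with the Cdc14b genotype. The Y-linked genes of the list, which are present only in XY cells, summed to 417 to 465 normalized counts in wild-type clone 1 and 512 to 546 in Cdc14a KO clone 1, against 69.1 to 201 in wild-type clone 3 and 68.4 to 89.8 in Cdc14a KO clone 3. In Cdc14b KO clones the sum was 4.44 to 65 and in Cdc14ab KO clones 14 to 57.1. Xist, the RNA that coats an inactive X chromosome, stayed at 8.69 or lower in wild-type and Cdc14a KO libraries and ranged over days from 4.75 to 44.6 and 6.67 to 16.9 in Cdc14b KO clones 1 and 3 and from 20.4 to 46.2 and 11.8 to 54.9 in Cdc14ab KO clones 1 and 3. At day 0 the median log2 difference from wild type of X-linked genes, minus that of autosomal genes, was 0.233 and 0.22 in the Cdc14ab KO clones and 0.201 and 0.101 in the Cdc14b KO clones. At day 7 it was -0.039 and -0.173 in the Cdc14ab KO clones and -0.059 and -0.142 in the Cdc14b KO clones. Comparisons of Cdc14b KO or Cdc14ab KO with wild type therefore also compared lines that differed in mean sex-chromosome transcript levels, although clone 3 was lower in Y-linked reads than clone 1 in wild type and Cdc14a KO as well. Wild-type clone 3 at day 7 was described as undifferentiated in 1 field of its record and as day 7 in others, and its median signed change over genes of the day 7 response was 1.73, against 1.46 to 1.94 in the other day 7 libraries.

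No difference of Cdc14a or Cdc14b between a knockout and wild type passed the test. Cdc14a was near the limit of detection everywhere, at 9.91 ± 4.1, 16.4 ± 16.5 and 9.19 ± 1.49 at days 0, 2 and 7 in wild type. It was at 14.1 ± 11, 17.2 ± 12.4 and 8.14 ± 2.3 in Cdc14a KO, 12.2 ± 4.63, 8.86 ± 2.97 and 6.74 ± 3.35 in Cdc14b KO. In Cdc14ab KO it was at 7.17 ± 4.18, 5.78 ± 2.09 and 6.94 ± 2.69. Cdc14b was at 123 ± 27.4, 202 ± 85.8 and 190 ± 9.77 in wild type, 153 ± 21.6, 273 ± 22 and 167 ± 3.72 in Cdc14a KO. It was at 248 ± 21.6, 154 ± 81.5 and 131 ± 35.5 in Cdc14b KO, and 286 ± 55.4, 174 ± 41.8 and 116 ± 21.6 in Cdc14ab KO. Reads from the 3′ end check a knockout only where the deletion removes that end or destabilizes the transcript, and the position of the deletions was not given in the sources used here, so these levels neither establish nor exclude the knockouts.

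Utf1 fell in wild type, and its changes in the 3 knockouts did not pass the test in limma. Wild type went from 2310 ± 924 at day 0 to 925 ± 180 at day 2 and 544 ± 188 at day 7 (day 7 against day 0, log2 fold change -2.07 ± 0.40, adjusted p = 0.0042). Without wild-type day 0 clone 3 the wild-type change was -1.65 (adjusted p = 0.076), and without wild-type day 7 clone 3 it was -1.71 (adjusted p = 0.11), so the call rested on those libraries. In Cdc14a KO, Utf1 was at 1690 ± 772, 948 ± 44.1 and 772 ± 25.5 (day 7 -1.05 ± 0.40, adjusted p = 0.1 in limma and 0.049 in DESeq2). It was at 1840 ± 801, 2280 ± 233 and 1790 ± 315 in Cdc14b KO (0.02 ± 0.40, adjusted p = 0.99). In Cdc14ab KO it was at 1320 ± 257, 1850 ± 318 and 1320 ± 467 (-0.04 ± 0.40, adjusted p = 0.96). The difference from wild type at day 7 did not pass the test in Cdc14ab KO (1.27 ± 0.40, adjusted p = 0.13) or in Cdc14b KO (1.75 ± 0.40, adjusted p = 0.17). DESeq2 gave adjusted p = 0.054 and 0.011 for these differences. The interaction, tested directly, was 2.03 ± 0.56 in Cdc14ab KO (adjusted p = 0.075 in limma and 0.016 in DESeq2). With only the groups compared in the fit, limma gave adjusted p = 0.2. Leaving out single libraries, the value ranged from 1.61 (without wild-type day 0 clone 3) to 2.45 (without wild-type day 0 clone 1). The interaction was 2.09 ± 0.56 in Cdc14b KO (adjusted p = 0.59) and 1.02 ± 0.56 in Cdc14a KO (adjusted p = 1).

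**Figure D2:**
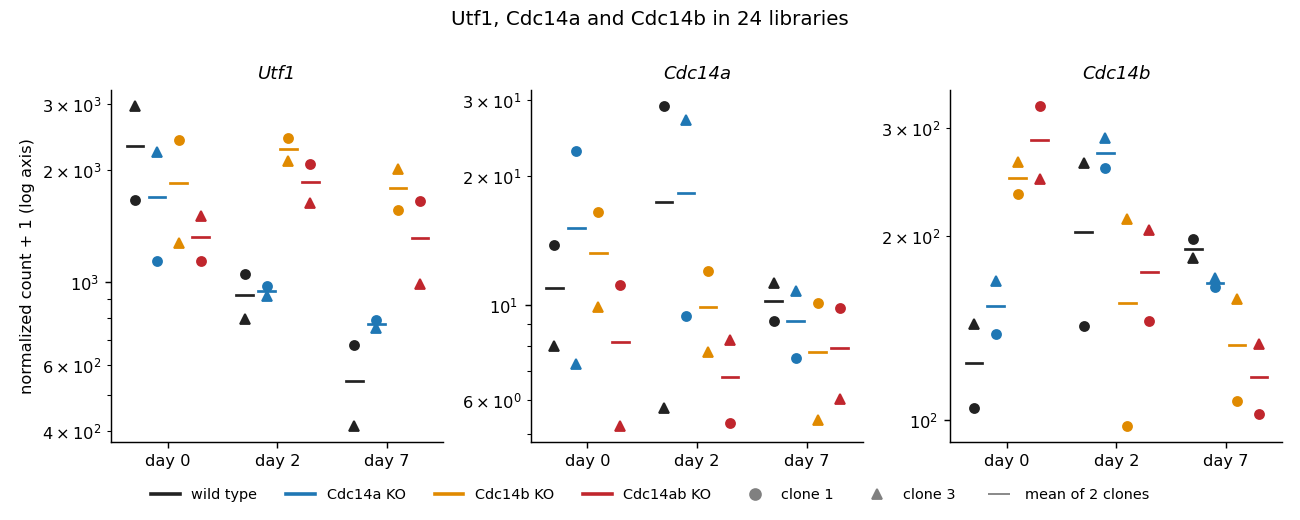
Points are single clones of the 4 genotypes at days 0, 2 and 7, with normalized count + 1 of Utf1, Cdc14a and Cdc14b on a log axis and bars at the mean of 2 clones. Utf1 went from a mean of 2310 to 544 normalized counts in wild type and from 1320 to 1320 in Cdc14ab KO.

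By day 2 in wild type Meis2, Pmp22 and Sox1 had risen and Klf5 and Tdgf1 had fallen. Meis2, a homeobox cofactor of Hox proteins, rose from 18.4 ± 13.2 to 438 ± 27.8 (25.8-fold, log2 4.69 ± 0.86, adjusted p = 0.02). Pmp22, a membrane protein of glia and neuroepithelium, rose 20.6-fold from 30.8 ± 15.3 to 620 ± 96.8 (adjusted p = 0.0029). Sox1, which marks neuroectoderm, rose from 12.7 ± 11.9 to 180 ± 27.9 (4.06 ± 0.62, adjusted p = 0.0083). Klf5, which sustains self-renewal, fell 4.8-fold from 1430 ± 393 to 292 ± 41.2 (adjusted p = 0.015). Tdgf1, the Nodal co-receptor, fell 3.87-fold from 1520 ± 84.8 to 394 ± 58.1 (adjusted p = 0.015). The Wnt antagonist Frzb (612 ± 309 against 10.8 ± 3.17), the eye-field factor Six6 (163 ± 121 against 3.01 ± 4.25), and Igfbp5 (168 ± 54.5 against 5.01 ± 7.08) rose. So did Hoxb1 (138 ± 67.8 against 3.14 ± 1.6), Dach1 (102 ± 15.5 at day 2) and Gpm6a (161 ± 124 against 8.08 ± 8.41). Krt17, Jam2 (18.7 ± 3.65 against 118 ± 9.36) and Icam1 (31.1 ± 5.65 against 149 ± 21.3) fell. limma called 57 of 16158 genes, 48 higher and 9 lower, and 112 with the clones paired across days. With only the groups compared in the fit it called 4, without the 3 libraries rich in Gm42418 reads 35, edgeR 29 and DESeq2 268. It called 7 without wild-type day 0 clone 1, without wild-type day 0 clone 3 or without wild-type day 2 clone 3, where the lone remaining clone was taken to vary like the other groups. None of the 27 named genes of this comparison kept its call in every fit that left out 1 library.

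Cholesterol synthesis was called as a list at day 2 in wild type and kept its call with an estimated correlation (adjusted p = 0.031). Of 24 cholesterol synthesis genes, 3 rose (Stard4, Msmo1 and Nsdhl), 0 fell and 21 did not pass, and 19 rose adjusted over the list alone (median 1.44, limma camera adjusted p = 4.8e-20). Msmo1, a sterol demethylase, went from 540 ± 11.7 to 2800 ± 1760, and Nsdhl from 44.7 ± 13.7 to 192 ± 48.7. Retinoic acid targets rose in 4 of 15 members and 10 adjusted over the list alone (median 2.63, camera adjusted p = 1.8e-12), among them Meis1 (242 ± 49.4 against 22.4 ± 7.58). Of 18 naive pluripotency genes, 1 fell, Klf5, and 10 fell adjusted over the list alone (median -2.01, camera adjusted p = 4.6e-14, adjusted p = 0.1 with an estimated correlation), with Tcl1 at 23.1 ± 11.2 against 181 ± 1.4 and Tdh at 875 ± 370 against 4740 ± 110. General pluripotency genes fell in 1 of 16, Tdgf1, and in 3 adjusted over the list alone (median -0.67, camera adjusted p = 4.4e-05, adjusted p = 0.2 with an estimated correlation). Neuron genes rose in 1 of 28, Onecut2 (201 ± 175 against 19.2 ± 1.59), and in 5 adjusted over the list alone (median 1.30, camera adjusted p = 2.9e-07, adjusted p = 0.29 with an estimated correlation). Neural progenitor genes rose in 1 of 23, Sox1, and in 4 adjusted over the list alone (median 1.01, camera adjusted p = 4.4e-05, adjusted p = 0.27 with an estimated correlation). Hox genes rose in 4 of 25 and in 9 adjusted over the list alone (median 1.58, camera adjusted p = 1.2e-08, adjusted p = 0.29 with an estimated correlation). Pairing the clones gave camera adjusted p = 0.04 for formative and primed pluripotency, 0.025 for endoderm, 0.044 for the 2-cell-like state and 0.033 for feeder fibroblast genes, which were 0.076, 0.066, 0.069 and 0.069 without pairing.

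By day 7 in wild type 13 of 28 neuron, 11 of 25 Hox and 10 of 15 retinoic acid target genes had risen. Nr2f1, an orphan nuclear receptor of hindbrain and cortex, rose 201-fold from 14.6 ± 7.96 to 3150 ± 1640 (7.65 ± 0.75, adjusted p = 4.2e-05). Nkx6-1, a factor of ventral progenitors, rose 40.8-fold from 22.7 ± 20.7 to 806 ± 388 (5.35 ± 0.85, adjusted p = 0.0012). Meis1 rose 44.5-fold from 22.4 ± 7.58 to 1070 ± 489 (5.48 ± 0.50, adjusted p = 2.4e-05). Map2, which stabilizes dendritic microtubules, rose 18-fold from 68.4 ± 10.4 to 1510 ± 1220 (adjusted p = 0.0034), and Dcx, the migrating-neuron protein, from 3.04 ± 2.79 to 520 ± 400. Trh, a releasing-hormone precursor abundant in stem cells, fell 16.7-fold from 1340 ± 430 to 79.9 ± 28.5 (-4.06 ± 0.74, adjusted p = 0.0033). Krt42 fell from 202 ± 138 to 12.3 ± 4.29, and Psmb9, an immunoproteasome subunit, from 97.6 ± 21.9 to 7.76 ± 1.1. limma called 1188 genes, 883 higher and 305 lower, with 1395 when clones were paired, 2189 with only the groups compared in the fit and 1854 in DESeq2. The count was 436 without wild-type day 0 clone 1, 372 without day 0 clone 3, 665 without day 7 clone 1 and 160 without day 7 clone 3. Of the named genes, 27 of the 80 called here kept their call without any 1 library.

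Of 28 neuron genes, 13 rose in wild type by day 7, 0 fell and 15 did not pass, and 15 rose adjusted over the list alone (median 2.13, camera adjusted p = 4.4e-10, adjusted p = 0.16 with an estimated correlation). Onecut2 reached 531 ± 335 and Elavl4, a neuronal RNA-binding protein, 415 ± 315. Of 23 neural progenitor genes 7 rose, 11 adjusted over the list alone, among them Irx3 (839 ± 162 against 69.4 ± 8.95) and Ptprz1 (117 ± 88.7 against 3.14), with median 1.80 (camera adjusted p = 1.3e-06, adjusted p = 0.15 with an estimated correlation). Hox genes rose in 11 of 25 and 15 adjusted over the list alone (median 3.42, camera adjusted p = 1e-09, adjusted p = 0.22 with an estimated correlation), with Hoxb4 at 656 ± 431 against 9.31. Retinoic acid targets rose in 10 of 15, 12 adjusted over the list alone (median 3.47, camera adjusted p = 9.4e-11), Nr2f2 going from 13.1 to 673 ± 467. Developmental regulators with bivalent promoters other than Hox rose in 22 of 88, 33 adjusted over the list alone, and none fell (median 1.69, camera adjusted p = 4.4e-10, adjusted p = 0.15 with an estimated correlation). Meis1 and Meis2 belong to both the bivalent and the retinoic acid lists.

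Some pluripotency genes fell at day 7 in wild type, while no pluripotency list was called with an estimated correlation. General pluripotency genes fell in 6 of 16, 11 adjusted over the list alone (median -1.31, camera adjusted p = 7.5e-07, adjusted p = 0.13 with an estimated correlation), including Utf1 and the adhesion protein Epcam (364 ± 109 against 1450 ± 128). Naive pluripotency genes fell in 2 of 18, Klf5 and Tdh (591 ± 109 against 4740 ± 110), and 3 adjusted over the list alone (median -1.20, camera adjusted p = 2.2e-05, adjusted p = 0.29 with an estimated correlation). Among 15 formative and primed pluripotency genes, Cdh2 rose (1010 ± 72.6 against 117 ± 48.4) and Dnmt3b, Etv5 and Tcf15 fell, and the list was not called (median -0.93, adjusted p = 0.16). G1-S and replication genes fell in 2 of 24, Ccne1 (-1.76 ± 0.44) and Mcm2 (-1.11 ± 0.32), with median -0.50 (camera adjusted p = 0.0013, and 0.045 with an estimated correlation). No mitosis gene passed, and that list had median -0.46 (camera adjusted p = 0.0017, adjusted p = 0.29 with an estimated correlation). The ATF4 and unfolded protein stress list had median -0.40 (camera adjusted p = 0.021, adjusted p = 0.29 with an estimated correlation), with Slc3a2, an amino acid transporter chain, down 1.89 ± 0.41. Mitochondrially encoded transcripts had median -0.62 with no gene passing (camera adjusted p = 0.025, adjusted p = 0.42 with an estimated correlation).

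Some genes outside the neural lineage rose in wild type as well. Imprinted genes, expressed from 1 parental allele, rose in 15 of 35 and fell in 1, with 19 and 2 adjusted over the list alone (median 1.41, camera adjusted p = 2.5e-07, and 0.0028 with an estimated correlation). H19, a growth-restraining noncoding RNA, rose 23-fold from 1070 ± 151 to 24600 ± 4480, and Asb4 rose from 5.67 to 241 ± 15.3. In the 2-cell-like state list 7 of 9 genes rose, 8 adjusted over the list alone with 1 lower (median 5.24, and 4.52 with bounded genes, camera adjusted p = 7.5e-07, adjusted p = 0.15 with an estimated correlation), with Zscan4c at 44.9 ± 28.5 from 0 and Duxf3 at 61.1 ± 13.9. Trophectoderm genes rose in 6 of 14, 7 adjusted over the list alone, including Gata3 (276 ± 45.2 against 24.8) and Krt7 (308 ± 16 against 25.1), with median 1.75 (camera adjusted p = 0.0016, adjusted p = 0.29 with an estimated correlation). Endoderm genes rose in 4 of 12, 6 adjusted over the list alone, with the basement-membrane collagen Col4a1 at 454 ± 63.6 against 47.8 ± 12.4 (median 1.47, camera adjusted p = 0.0022, adjusted p = 0.22 with an estimated correlation). Feeder fibroblast genes rose in 4 of 25, 7 adjusted over the list alone (median 1.92, camera adjusted p = 0.00059, adjusted p = 0.45 with an estimated correlation), with Col1a1 at 1920 ± 577 against 117 ± 113. The cells had been grown on feeders before day 0. Among 26 germline genes Stra8, a retinoic acid induced meiotic gene, rose 25.8-fold from 151 ± 84.9 to 3760 ± 1500 and Sycp3 fell (median 1.10, camera adjusted p = 0.023, adjusted p = 0.55 with an estimated correlation).

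The remaining lists were not called at day 7 in wild type: glia (median 1.03, adjusted p = 0.42), mesoderm (1.02, 0.36), p53 targets (-0.16, 0.42), Y-linked genes and Xist (0.96, 0.47), cholesterol synthesis (0.35, 0.46), hypoxia and glycolysis (0.13, 0.66), Wnt targets (-0.44, 0.4), Nodal and TGF-beta targets (-0.87, 0.09), BMP targets (-0.15 against a mean of 0.18, 0.67), FGF-ERK targets (-0.19, 0.19) and the UTF1 and Cdc14 family (-0.05, 0.39). Single members still passed: Foxc1, a mesodermal forkhead factor, rose from 9.81 to 403 ± 191, Id4 rose by 2.61 ± 0.71, and Apoe fell by 1.76 ± 0.38.

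In cells lacking both phosphatases Pmp22, Irx3, Sox1 and Stra8 rose by day 2, without a call of the neural lists. Pmp22 rose 14.7-fold from 22.2 ± 13.4 to 311 ± 42.5 (3.88 ± 0.57, adjusted p = 0.0077), Irx3 rose from 31 ± 8.05 to 370 ± 95.2 (3.53 ± 0.60, adjusted p = 0.017), and Stra8 rose 28.3-fold from 39.7 ± 8.34 to 1390 ± 1130 (adjusted p = 0.022). Sox1 rose by 3.00 ± 0.62, and Frzb (229 ± 215 against 6.86 ± 9.7), Ppp2r2c (411 ± 2.92 against 41.9 ± 1.95) and Greb1l (436 ± 89.1 against 48.3 ± 9.27) rose. Trh fell from 3510 ± 1410 to 297 ± 78.2, the Hedgehog effector Gli1 from 1740 ± 351 to 308 ± 193, and Mirg, a noncoding RNA of the imprinted Dlk1-Dio3 region, from 2230 ± 1190 to 334 ± 54.6. Cholesterol synthesis genes rose in 2 of 24, Fdft1 (2910 ± 679 against 681 ± 90) and Ebp, and 12 adjusted over the list alone (median 1.24, camera adjusted p = 2.6e-09, adjusted p = 0.41 with an estimated correlation). Retinoic acid targets rose in 2 of 15, Stra8 among them, and 8 rose and 1 fell adjusted over the list alone (median 1.82, camera adjusted p = 8.3e-06, adjusted p = 0.41 with an estimated correlation). No neuron gene passed (median 0.21, and -0.03 with bounded genes, adjusted p = 0.89), and neural progenitor genes rose in 2 of 23 with median 0.23 (adjusted p = 0.44). limma called 52 genes, 29 higher and 23 lower, and 172 with clones paired. With only the groups compared in the fit it called 0, without the 3 libraries rich in Gm42418 reads 1, with clone as a random effect 80, edgeR 24 and DESeq2 802. The count was 2442 without Cdc14ab KO day 0 clone 3, 1 without Cdc14ab KO day 0 clone 1, 9 without Cdc14ab KO day 2 clone 1 and 0 without Cdc14ab KO day 2 clone 3, so the extent of this change was set by single libraries. None of the 25 named genes called here kept its call in every fit that left out 1 library.

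At day 7, Cdc14ab KO cells had lower levels of several pluripotency genes and raised keratins and other trophectoderm genes, with few neuronal genes raised. Pou5f1, the core factor of pluripotency, fell from 32600 ± 9130 to 6740 ± 1940 (-2.28 ± 0.49, adjusted p = 0.006), and Lin28a from 2950 ± 1270 to 583 ± 20.6 (-2.27 ± 0.47, adjusted p = 0.005). Trh fell from 3510 ± 1410 to 21.5 ± 19.7 (-7.58 ± 0.74, adjusted p = 2.4e-05). Krt8 and Krt7, keratins of simple epithelia and trophectoderm, rose from 216 ± 31 to 5770 ± 5620 and from 27.9 ± 3.57 to 1680 ± 1740. Neurod1, a neuronal bHLH factor, fell from 96.4 ± 48.7 to 10.4 ± 7.55 (-3.18 ± 0.54, adjusted p = 0.0013), and the intermediate filament Ina from 465 ± 122 to 40.9 ± 11.6. Irx3 (2640 ± 2830 against 31) and Stra8 (81.9-fold, 4260 ± 3820 against 39.7 ± 8.34) rose. So did Rhox9 (11500 ± 10500 against 172 ± 200) and Vnn1 (128 ± 33.2 at day 7), and Slc27a2 fell (111 ± 17.5 at day 0). limma called 2722 genes, 1536 higher and 1186 lower, but 52 with only the groups compared in the fit and 304 without the 3 libraries rich in Gm42418 reads. Of 105 named genes called here, 39 kept their call without any 1 library. The count was 401 without Cdc14ab KO day 0 clone 1, 4299 without day 0 clone 3 and 554 without day 7 clone 3.

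Trophectoderm genes rose in 11 of 14 in Cdc14ab KO by day 7, also adjusted over the list alone (median 3.92, camera adjusted p = 3.5e-08, adjusted p = 0.17 with an estimated correlation), with Krt19 at 1220 ± 1160 against 35.8. Endoderm genes rose in 6 of 12, 8 adjusted over the list alone, among them Col4a2 (634 ± 526 against 23.8) and the growth factor Pdgfa (2520 ± 1250 against 577 ± 191), with median 2.01 (camera adjusted p = 0.00015, adjusted p = 0.17 with an estimated correlation). Of 28 neuron genes 3 rose and 8 fell, 3 and 9 adjusted over the list alone (median -1.01, and -0.81 with bounded genes, camera adjusted p = 0.029, adjusted p = 0.7 with an estimated correlation). Neural progenitor genes were split between Irx3 up and Notch1 down (median -0.03, adjusted p = 0.71). Formative and primed pluripotency genes fell in 5 of 15, 8 adjusted over the list alone, including Pou3f1 and Dnmt3b (median -1.46, camera adjusted p = 0.00031, adjusted p = 0.17 with an estimated correlation). General pluripotency genes fell in 6 of 16, 9 adjusted over the list alone (median -0.94, camera adjusted p = 0.00031, adjusted p = 0.25 with an estimated correlation). Mitochondrially encoded transcripts fell in 8 of 13, 9 adjusted over the list alone, with mt-Atp6 at 38.7 ± 20 against 556 ± 520 (median -1.10, camera adjusted p = 3e-04, adjusted p = 0.25 with an estimated correlation). Retinoic acid targets rose in 9 of 15 and fell in 1, 12 and 1 adjusted over the list alone (median 2.73, camera adjusted p = 4.6e-06, adjusted p = 0.17 with an estimated correlation). 2-cell-like state genes rose in 7 of 9 (median 4.05, and 2.75 with bounded genes, camera adjusted p = 3e-04, adjusted p = 0.32 with an estimated correlation). Of 35 imprinted genes 10 rose and 5 fell, and the list was not called (median 0.39, adjusted p = 0.17). H19 rose from 601 ± 293 to 29200 ± 17700 and Cdkn1c, a cyclin-dependent kinase inhibitor, from 192 to 5210 ± 5380. Rian fell from 3990 ± 607 to 429 ± 37.4 and Mirg from 2230 ± 1190 to 169 ± 29.9.

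Cells lacking Cdc14a alone had a day 7 response close to that of wild type (correlation 0.84 across genes). The correlation with wild type was 0.59 for Cdc14b KO and 0.38 for Cdc14ab KO. The day 0 mean of Cdc14ab KO includes clone 1, the library that stood apart, and 0.38 was not recomputed without it. Nr2f1 rose from 8.65 to 2480 ± 1850 (7.77 ± 0.75, adjusted p = 3.7e-05), Nkx2-3 from 3.5 ± 2.41 to 773 ± 182 and the T-cell and neural factor Tox2 from 19.3 ± 9.58 to 2190 ± 1400 (6.68 ± 0.75, adjusted p = 9.5e-05). Trh fell from 2470 ± 38.2 to 32 ± 22.3 (-6.41 ± 0.74, adjusted p = 1e-04) and Krt42 from 221 ± 139 to 10 ± 1.91. Neuron genes rose in 9 of 28, 14 adjusted over the list alone, led by Onecut2 (311 ± 107 against 3.8 ± 0.968) and Elavl4 (271 ± 164 against 14.8 ± 1.87), with median 1.80 (camera adjusted p = 1.8e-06, adjusted p = 0.25 with an estimated correlation). Neural progenitor genes rose in 7 of 23, 8 adjusted over the list alone, among them Nkx6-1 (621 ± 437 against 36.7 ± 29), with median 1.30 (camera adjusted p = 2e-04, adjusted p = 0.24 with an estimated correlation). G1-S and replication genes fell in 4 of 24, including Rrm2 (-1.42 ± 0.30) and Mcm2 (-1.48 ± 0.32), with median -0.72 (camera adjusted p = 0.00015, and 0.022 with an estimated correlation). Imprinted genes rose in 13 of 35 and fell in 2 (median 1.15, camera adjusted p = 9.7e-06, and 0.0095 with an estimated correlation). limma called 1497 genes, 1015 higher and 482 lower, with 2416 when only the groups compared were fitted and 2309 in DESeq2. Of 82 named genes called here, 38 kept their call without any 1 library. The count was 297 without Cdc14a KO day 0 clone 1, 805 without day 0 clone 3, 559 without day 7 clone 1 and 332 without day 7 clone 3.

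In cells lacking Cdc14b alone the neuronal part of the course was mixed. Dcx rose from 0.594 to 118 ± 133 and Onecut2 rose by 2.32 ± 0.62. Neurod1 fell from 194 ± 36.7 to 15.5 ± 0.386 (-3.55 ± 0.54, adjusted p = 0.0014). Of 28 neuron genes 3 rose and 1 fell, 5 and 5 adjusted over the list alone, and the list was not called (median 0.02 and mean 0.33 with a downward test direction, adjusted p = 0.98). Neural progenitor genes rose in 3 of 23, Irx3 (819 ± 332 against 43.9 ± 11.8) and Sox1 (3.51 ± 0.62) among them (median 0.65, and 0.60 with bounded genes, adjusted p = 0.061). Tmem92 (268 ± 109 against 1.19) and 7 other genes of the 9 in the 2-cell-like state list rose (median 4.84, and 4.83 with bounded genes, camera adjusted p = 1.2e-09, adjusted p = 0.13 with an estimated correlation). Trophectoderm genes rose in 5 of 14, 10 adjusted over the list alone, with Krt7 at 347 ± 9.14 against 15.5 ± 1.71 (median 2.65, camera adjusted p = 4e-08, adjusted p = 0.13 with an estimated correlation). H19 rose from 514 ± 245 to 27100 ± 7070 and Stra8 from 102 ± 78.7 to 4560 ± 1110. In turn mt-Rnr1, the small mitochondrial ribosomal RNA, fell from 10800 ± 72.1 to 2060 ± 333 (-2.39 ± 0.41, adjusted p = 0.003). limma called 746 genes, 411 higher and 335 lower, with 207 without the 3 libraries rich in Gm42418 reads and 1247 in DESeq2. Of 67 named genes called here, 20 kept their call without any 1 library. The count was 251 without Cdc14b KO day 0 clone 1, 178 without day 0 clone 3, 345 without day 7 clone 1 and 221 without day 7 clone 3.

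**Figure D3:**
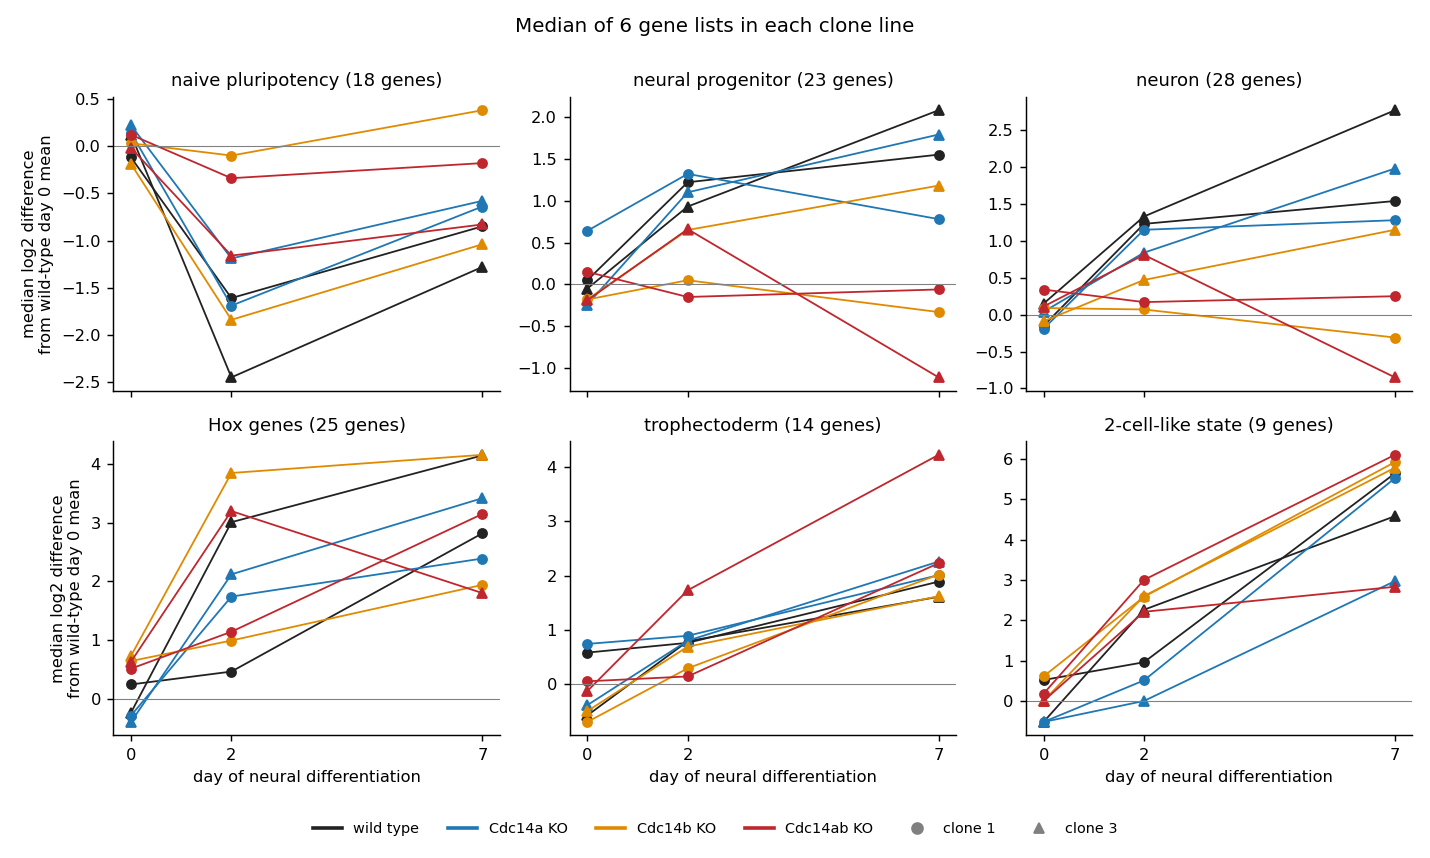
Lines join the days (horizontal axis) of single clones, coloured by genotype, and the vertical axis is the median log2 difference of 6 gene lists from the wild-type day 0 mean. The neuron list (28 genes) rose to 1.54 and 2.77 in the wild-type clones at day 7.

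At days 0 and 2 no gene differed between Cdc14ab KO and wild type by limma. At day 0 edgeR called 0, DESeq2 447, and 2564 genes had an unadjusted p under 0.05, against 808 expected by chance. At day 2 edgeR and DESeq2 called 0, and 248 genes had an unadjusted p under 0.05, fewer than the 808 expected by chance. Cdc14b stood 1.22 ± 0.39 above wild type at day 0 (adjusted p = 0.14). The day 0 count was 2228 without Cdc14ab KO day 0 clone 3 and 0 without any other library. At day 2 the lists differed although single genes did not. The 18 naive pluripotency genes had median 1.04 (camera adjusted p = 1.1e-12, adjusted p = 0.22 with an estimated correlation), with Tbx3, a regulator of self-renewal, at 196 ± 58.8 against 36.5 ± 19.5 (2.47 ± 0.69, adjusted p = 1). Neuron genes had median -0.84 (camera adjusted p = 5.6e-12, adjusted p = 0.22 with an estimated correlation) with Neurod1 at -1.71 ± 0.54 (adjusted p = 1). Neural progenitor genes had median -0.49 (camera adjusted p = 5.4e-06, adjusted p = 0.22 with an estimated correlation) and general pluripotency genes 0.53 (camera adjusted p = 2.5e-05, adjusted p = 0.22 with an estimated correlation). Y-linked genes and Xist moved with them (median -2.55, camera adjusted p = 0.00096, adjusted p = 0.22 with an estimated correlation).

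At day 7, 234 genes were lower in Cdc14ab KO than in wild type, among them 15 of 28 neuron and 5 of 23 neural progenitor genes. Ly6h, a neuronal membrane protein that binds acetylcholine receptors, was at 57.4 ± 46.7 against 3030 ± 1530, 58.8-fold lower (-5.88 ± 0.80, adjusted p = 0.011). Gpm6a, a neurite-outgrowth glycoprotein, was at 5.12 ± 2.49 against 288 ± 144 (46.1-fold lower, -5.53 ± 0.90, adjusted p = 0.012). Nkx6-1 was at 18.3 ± 3.31 against 806 ± 388 (39.6-fold lower, -5.31 ± 0.85, adjusted p = 0.012). Tead4, the trophectoderm-specifying factor, was 4.56-fold higher at 223 ± 123 against 45.4 ± 14.7 (2.19 ± 0.51, adjusted p = 0.035). Arap1, a regulator of Arf proteins, was 5.31-fold higher at 229 ± 74.5 against 41.1 ± 2.65 (2.41 ± 0.55, adjusted p = 0.035). limma called 247 of 16158 genes, 13 higher and 234 lower, edgeR called 190 and DESeq2 650. Fitted with 1 clone-number offset over all genotypes and days, limma called 376, 27 higher and 349 lower. With only the groups compared in the fit limma called 0, without the 3 libraries rich in Gm42418 reads 114, and with a filter of 50 normalized counts 163. The count was 0 without wild-type day 7 clone 3, 0 without Cdc14ab KO day 7 clone 3 and 517 without Cdc14ab KO day 7 clone 1. Of the 37 named genes called here, 34 kept their call without Cdc14ab KO day 7 clone 1, 23 without wild-type day 7 clone 1, and 0 without either clone 3 library.

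**Figure D4:**
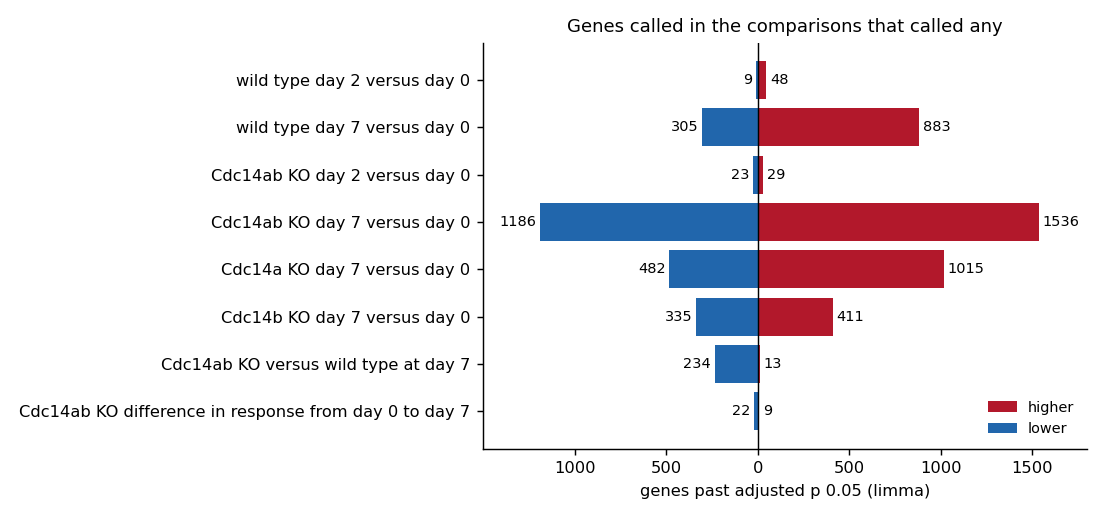
Bars give the number of genes that passed adjusted p 0.05 in limma, higher to the right and lower to the left, for the 8 comparisons with any such gene. Cdc14ab KO against wild type at day 7 had 13 higher and 234 lower, while the day 7 course of Cdc14ab KO had 1536 and 1186.

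Of 28 neuron genes, 15 were lower in Cdc14ab KO than in wild type at day 7, 0 higher and 13 did not pass, and 27 were lower adjusted over the list alone (median -2.99, and -2.89 with bounded genes, camera adjusted p = 4.9e-29, adjusted p = 0.061 with an estimated correlation). Map2 was 18-fold lower at 70.2 ± 24.4 against 1510 ± 1220, Onecut2 was at 52.6 ± 2.01 against 531 ± 335, Elavl4 at 30.3 ± 15.5 against 415 ± 315 and Neurod1 at 10.4 ± 7.55 against 83.2 ± 50.2. Of 23 neural progenitor genes 5 were lower and 12 adjusted over the list alone (median -1.73, camera adjusted p = 1.8e-10, adjusted p = 0.082 with an estimated correlation), among them the Notch effector Hes5 (21.6 ± 13.9 against 947 ± 968), Sox11 (882 ± 439 against 9680 ± 6440) and Ptprz1 (3.93 ± 5.56 against 117 ± 88.7). The mesodermal and spinal factor Lhx1 was at 6.24 ± 6.45 against 288 ± 286, and Chodl at 4.91 ± 6.95 against 246 ± 181. Bivalent developmental regulators other than Hox were lower in 6 of 88 and 20 adjusted over the list alone (median -0.94, camera adjusted p = 4.3e-07, adjusted p = 0.28 with an estimated correlation), with Meis1 at 196 ± 12.8 against 1070 ± 489. Hox genes were lower in 1 of 25, Hoxa2, and 5 adjusted over the list alone (median -1.17, camera adjusted p = 0.0053, adjusted p = 0.6 with an estimated correlation). Retinoic acid targets were lower in 2 of 15, Nr2f1 (274 ± 183 against 3150 ± 1640) and Meis1 (median -1.11, camera adjusted p = 0.027, adjusted p = 0.59 with an estimated correlation). Id4, an inhibitor of bHLH factors, was lower by 3.99 ± 0.71.

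Of 14 trophectoderm genes, Tead4 alone passed as higher in Cdc14ab KO than in wild type at day 7, also adjusted over the list alone (median 1.43, camera adjusted p = 5.7e-06, adjusted p = 0.24 with an estimated correlation). Tfap2c was at 7120 ± 2680 against 1930 ± 725 (1.88 ± 0.65, adjusted p = 0.2) and Krt8 at 5770 ± 5620 against 1410 ± 175 (1.58 ± 0.77, adjusted p = 0.42). The list median, relative to wild-type day 0, was 2.23 in Cdc14ab KO clone 1 and 4.23 in clone 3, against 1.61 to 2.26 in the other day 7 libraries, so clone 3 carried the difference. Dusp9 (7700 ± 5610 against 1600 ± 567), a phosphatase that restrains ERK, the epithelial protease St14 (456 ± 228 against 100 ± 7.82) and Pdgfa (2520 ± 1250 against 793 ± 175) were higher. Of 18 naive pluripotency genes 0 passed and 1 was higher adjusted over the list alone, Klf5 at 663 ± 192 against 226 ± 18.5 (median 0.69, and 0.62 with bounded genes, camera adjusted p = 0.0072, adjusted p = 0.59 with an estimated correlation). General pluripotency (median 0.10, adjusted p = 0.2), mitosis (0.04, 0.99), G1-S and replication (0.10, 0.7), p53 targets (0.07, 0.58) and cholesterol synthesis (0.00, 0.64) were not called. Formative and primed genes were lower in 3 of 15, among them Cdh2 (159 ± 146 against 1010 ± 72.6), with median -0.73 (camera adjusted p = 0.0065, adjusted p = 0.22 with an estimated correlation). Imprinted genes were lower in 2 of 35, Nnat and Asb4 (-2.89 ± 0.69), and 1 higher and 9 lower adjusted over the list alone (median -0.29, camera adjusted p = 0.0053, adjusted p = 0.08 with an estimated correlation). Beside these groups, feeder fibroblast genes had median -1.49 with 0 of 25 passing (camera adjusted p = 0.0016, adjusted p = 0.59 with an estimated correlation), and Y-linked genes and Xist had median -2.28 (adjusted p = 0.065).

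**Figure D5:**
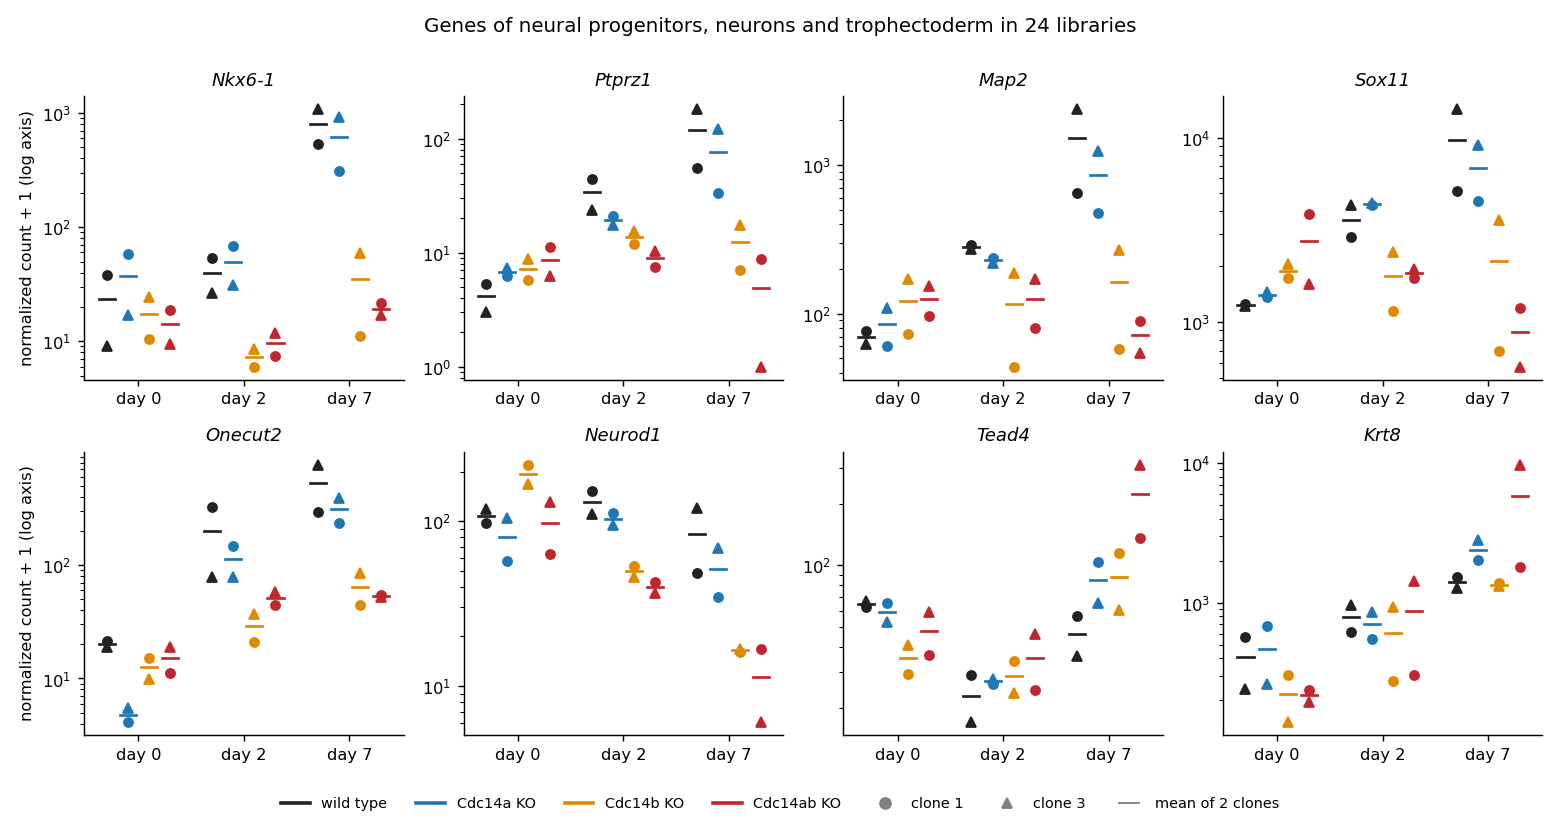
Points are single clones at days 0, 2 and 7 for 8 genes, with normalized count + 1 on a log axis, colours for genotypes and bars at the mean of 2 clones. At day 7 Nkx6-1 was at 806 normalized counts in wild type, 621 in Cdc14a KO, 34.4 in Cdc14b KO and 18.3 in Cdc14ab KO.

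Loss of Cdc14a alone gave no called gene against wild type at any day. limma, edgeR and DESeq2 each called 0 genes at days 0, 2 and 7. In limma 203, 150 and 70 genes had an unadjusted p under 0.05, against 808 expected by chance. So few small p-values mean that the test was cautious here, and a count of 0 does not show that an effect was absent. Deviations of same-numbered clones correlated between wild type and Cdc14a KO at 0.512, 0.055 and 0.541 at days 0, 2 and 7. A pairing by number within each day was not fitted. At day 7 Utf1 was 0.55 above wild type (adjusted p = 1). Naive pluripotency genes had median 0.76 with none passing (camera adjusted p = 5.4e-08, adjusted p = 0.47 with an estimated correlation). Neuron genes had median -0.47 (camera adjusted p = 0.00032, adjusted p = 0.76 with an estimated correlation). At day 2 only mitochondrially encoded transcripts were called as a list (median 0.25, camera adjusted p = 0.0032, adjusted p = 0.95 with an estimated correlation).

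Loss of Cdc14b alone gave no called gene against wild type, while 12 lists were called at day 7 and 2 with an estimated correlation. At day 7 Nkx6-1 was at 34.4 ± 34.3 against 806 ± 388 in wild type (-4.88 ± 0.85, adjusted p = 0.14), Onecut2 at 63.7 ± 28.6 against 531 ± 335 (-2.95 ± 0.62, adjusted p = 0.17) and the neurofilament Nefl at 58.8 ± 43 against 721 ± 538 (-3.58 ± 0.81, adjusted p = 0.17). Of 28 neuron genes 0 passed and 20 were lower adjusted over the list alone (median -2.20, camera adjusted p = 7.8e-19, adjusted p = 0.083 with an estimated correlation). Neural progenitor genes had median -1.33, and -1.32 with bounded genes (camera adjusted p = 6.5e-06, adjusted p = 0.22 with an estimated correlation). General pluripotency genes had median 0.57 (camera adjusted p = 2.9e-05, adjusted p = 0.22 with an estimated correlation), with Utf1 1.75 ± 0.40 above wild type. G1-S and replication genes had median 0.31 (camera adjusted p = 0.00073, and 0.044 with an estimated correlation), Rrm2 being 1.25 ± 0.30 above wild type. Imprinted genes had median -0.74 (camera adjusted p = 0.0023, and 0.044 with an estimated correlation). At day 2 naive pluripotency genes had median 0.99 (camera adjusted p = 4.7e-09, adjusted p = 0.21 with an estimated correlation). Neuron genes had median -0.98 (camera adjusted p = 8.4e-11, adjusted p = 0.21 with an estimated correlation). limma and edgeR called 0 genes at each day. DESeq2 called 2, 7 and 167 at days 0, 2 and 7. In limma 425, 389 and 1722 genes had an unadjusted p under 0.05, against 808 expected by chance. The day 7 count was 65 without Cdc14b KO day 7 clone 3 and 8 with a pseudocount of 5, and the day 0 count was 1 with only the groups compared in the fit. Y-linked genes and Xist were called at day 0 (median -3.22, and -1.81 with bounded genes, camera adjusted p = 0.0012, adjusted p = 0.28 with an estimated correlation).

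Tested directly as an interaction, the response to 7 days of differentiation differed between Cdc14ab KO and wild type for 31 genes. Among the lower ones were 1 gene of the neuron list and 1 of the neural progenitor list. Ly6h went from 70.7 ± 43.2 to 57.4 ± 46.7 in Cdc14ab KO and from 40.4 ± 25.9 to 3030 ± 1530 in wild type (difference -6.68 ± 1.13, adjusted p = 0.035). Stmn3, a neuronal microtubule regulator, went from 105 ± 68.7 to 31 ± 11.8 against 15.9 ± 7.33 to 215 ± 143 (-5.17 ± 0.97, adjusted p = 0.035). Gpm6a (-6.71 ± 1.27), the splicing factor Nova1 (-5.31 ± 0.77), Ptprz1 (-6.15 ± 1.24) and Id4 (-5.20 ± 1.01) gave the same direction. Rian (-3.44 ± 0.64) and Mirg (-3.03 ± 0.60), both of the imprinted Dlk1-Dio3 region, fell in Cdc14ab KO from day 0 levels of 3990 ± 607 and 2230 ± 1190, which were 1260 ± 478 and 576 ± 49.9 in wild type, a day 0 difference that was not called. Arap1 (4.20 ± 0.78), Psmb9 (5.51 ± 1.00), Nr6a1 (3.04 ± 0.57), Slc3a2 (2.97 ± 0.58) and Piezo1 (2.77 ± 0.53) differed upwards. Of 28 neuron genes 1 was lower, Stmn3, and 20 adjusted over the list alone (median -3.12, and -3.17 with bounded genes, camera adjusted p = 6.1e-14, adjusted p = 0.28 with an estimated correlation). Of 23 neural progenitor genes 1 was lower, Ptprz1, and 7 adjusted over the list alone (median -1.79, camera adjusted p = 0.00019, adjusted p = 0.62 with an estimated correlation). limma called 31 genes, 9 higher and 22 lower, edgeR 29 and DESeq2 957. It called 0 with only the groups compared in the fit and 0 without the 3 libraries rich in Gm42418 reads, but 85 with a pseudocount of 5, 62 with a filter of 50 normalized counts and 126 with clone as a random effect. It called 267 with clones paired, when the naive and formative lists were also called (adjusted p = 0.048 and 0.023). The count was 1 without wild-type day 0 clone 1, 19 without wild-type day 7 clone 1, and 205 without Cdc14ab KO day 7 clone 1. It was 1971 without Cdc14ab KO day 0 clone 3, and 0 without wild-type day 0 clone 3, wild-type day 7 clone 3, Cdc14ab KO day 0 clone 1 or Cdc14ab KO day 7 clone 3. None of the 20 named genes called here kept its call in every fit that left out 1 library.

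The response to day 2 in Cdc14ab KO and the responses to day 7 in the single knockouts gave no called gene. Utf1 had interaction values of 1.76 ± 0.56 (Cdc14ab KO, day 2), 1.02 ± 0.56 (Cdc14a KO, day 7) and 2.09 ± 0.56 (Cdc14b KO, day 7). limma, edgeR and DESeq2 called 0 in each. In limma 1386, 119 and 1278 genes had an unadjusted p under 0.05, against 808 expected by chance. limma called 90 in the day 2 interaction without wild-type day 2 clone 1, 888 without Cdc14ab KO day 0 clone 3, and 4 in the Cdc14b KO interaction without Cdc14b KO day 7 clone 3. In the Cdc14b KO interaction neuron genes had median -1.97, and -2.49 with bounded genes (camera adjusted p = 7.5e-13, adjusted p = 0.34 with an estimated correlation). Imprinted genes had median -0.85 (camera adjusted p = 3.6e-05, and 0.01 with an estimated correlation). With clones paired, germline genes were called in the day 2 interaction of Cdc14ab KO (adjusted p = 0.017), formative and primed genes in the Cdc14a KO interaction (0.047). The same pairing called Hox and germline genes in the Cdc14b KO interaction (0.042 and 0.03), where general pluripotency was lost (0.054).

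Against the mean of the single knockouts, Cdc14ab KO had no called gene at any day. limma and edgeR called 0, and DESeq2 called 30, 0 and 115 at days 0, 2 and 7. In limma 1848, 95 and 1034 genes had an unadjusted p under 0.05, against 808 expected by chance. At day 7 neuron genes had median -1.62, and -1.54 with bounded genes, with 0 of 28 passing and 17 lower adjusted over the list alone (camera adjusted p = 3.1e-22, adjusted p = 0.15 with an estimated correlation). Trophectoderm genes had median 1.24 (camera adjusted p = 2.2e-07, adjusted p = 0.17 with an estimated correlation). Utf1 was 0.12 above the mean of the single knockouts. The day 0 count was 1699 without Cdc14ab KO day 0 clone 3, and the day 7 count was 204 without Cdc14ab KO day 7 clone 1 and 10 without Cdc14b KO day 7 clone 1.

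Genes of the common day 7 response moved by about as much in Cdc14ab KO as in wild type. They were picked by the mean change of Cdc14a KO and Cdc14b KO, so genes that respond little without Cdc14b tend to be left out. Over 2544 genes picked in a fit of the single knockouts alone for the day 7 response (1631 rising and 913 falling), the median signed change was 1.65 ± 0.06 in wild type and 1.59 ± 0.14 in Cdc14ab KO, a difference of -0.06 against a pooled SD of 0.11. At day 2, over 539 genes (344 rising and 195 falling), it was 1.70 ± 0.29 in wild type and 1.42 ± 0.04 in Cdc14ab KO, a difference of -0.29 against 0.21. Of the genes called at day 7 in both genotypes, 321 rose in both (83.9 by chance) and 106 fell in both (22.4), and 7 rose in wild type and fell in Cdc14ab KO. Neuron genes departed from this common response: the list median from day 0 to day 7 was 1.53 and 3.08 in wild-type clones 1 and 3. It was 1.32 and 2.25 in Cdc14a KO, -0.46 and 0.64 in Cdc14b KO, and -0.29 and -1.29 in Cdc14ab KO.

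The day 7 effect of the double knockout correlated more with that of Cdc14b KO than with that of Cdc14a KO, over ranges that overlapped when single libraries were left out. Across genes, which are not independent replicates, the effects against the shared wild type correlated at 0.73 for Cdc14ab KO with Cdc14b KO (covariance 0.588 against 0.226 simulated with no effect), 0.43 for Cdc14ab KO with Cdc14a KO (0.186) and 0.23 for Cdc14a KO with Cdc14b KO (0.088). With 2 controls per day the controls cannot be split, and part of any excess may come from their sharing. Without single libraries the day 7 correlations ranged from 0.51 to 0.82, from 0.22 to 0.66 and from 0.05 to 0.56. At day 0 the 3 correlations were 0.59, 0.49 and 0.42, and at day 2 0.74, 0.22 and 0.19. Sharing the controls alone gave 0.5 in simulations without any effect, so correlations at or below that value do not show a common effect. The simulations left out the resemblance of same-numbered clones on the same day, so their values are an approximate reference. Of the 234 genes lower in Cdc14ab KO than in wild type at day 7, 111 rose with differentiation in Cdc14a KO (14.7 by chance) and 18 in Cdc14b KO (6). Nr2f1 and Nkx6-1 were among the genes that rose in Cdc14a KO.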

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

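Of the tests used here, those of 1 deciding library and of a second active X chromosome were chosen before the results were seen, and those of Y chromosome content, of the extent of the response, of clone numbers, of partner genotypes and of the day 7 label were chosen after.

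Calls of single genes in the day 7 interaction depended on single libraries, and limma called no gene with only the groups compared in the fit. With all libraries, limma called 31 genes whose response to 7 days of differentiation differed between Cdc14ab KO and wild type. Of the 22 with the larger fall or smaller rise in Cdc14ab KO, those named by rule were Gpm6a (-6.71), Ly6h (-6.68), Ptprz1 (-6.15), Pdgfc (-5.85), Hist3h2ba (-5.64), Nova1 (-5.31), Id4 (-5.20), Stmn3 (-5.17), Smpd3 (-4.97), Soga3 (-4.77), Rian (-3.44) and Mirg (-3.03). Of the 9 with the opposite difference, those named by rule were Psmb9 (5.51), Arap1 (4.20), Asb8 (3.83), Ppp2r2c (3.30), Nr6a1 (3.04), Slc3a2 (2.97), Chmp2a (2.93) and Piezo1 (2.77).

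Lower neuronal transcripts in Cdc14ab KO at day 7 may reflect 1 library, Y chromosome content, a smaller overall response or a real block of neural fate. Every pair of 1 Cdc14ab KO clone and 1 wild-type clone had a neuron list median of -1.67 or lower (-2.53, -3.54 and -4.22 in the others), which argues against 1 deciding library for the group, although the count of single genes was 0 without either clone 3 library. Over the 234 lower genes clone 3 exceeded clone 1 by 1.07 in wild type and 0.92 in Cdc14a KO, where it had less Y-linked RNA, and at day 7 Cdc14a KO clone 3 (Y-linked sum 68.4, median level 154) stood far above Cdc14ab KO clone 3 (57.1 and 9.65). These genes were picked in the day 7 libraries of wild type and Cdc14ab KO. Of these values only those of Cdc14a KO are free of that picking, and its 0.92 goes against Y content. Where both clones had little Y-linked RNA, however, clone 3 minus clone 1 was 1.33 in Cdc14b KO and -0.85 in Cdc14ab KO. Clones alike in Y-linked RNA thus differed as much, and Y content stays open (Cdc14a KO minus Cdc14b KO, -0.41). Over genes picked in the single knockouts, the median signed change of Cdc14ab KO was 96.4% of that of wild type. That argues against a smaller response of those genes. Genes that respond little without Cdc14b tend to be missed by that picking, so a smaller response over all genes stays open. A second active X chromosome stays open as well. X-linked minus autosomal genes differed between Cdc14ab KO and wild type by 0.23 at day 0 and -0.11 at day 7. Inactivation of 1 X chromosome during differentiation would also remove an excess by day 7, so the day 7 value cannot decide. Such an inactivation was not seen in Xist. At days 0, 2 and 7 Xist was at 27.8, 20.4 and 46.2 in Cdc14ab KO clone 1. In clone 3 it fell, from 54.9 to 13.1 and 11.8.

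Libraries of 1 clone number resembled each other across genotypes: 20 of 24 had a nearest library of the same day with the same number (mean 11 over 4096 relabellings, exact p = 0.012). The numbers were exchanged separately at each day, although a clone of 1 genotype is the same line over the days. Its libraries are not independent, so the p of 0.012 overstates the evidence. The resemblance fits a batch of culture or library preparation shared by number. Of the wild-type and Cdc14a KO libraries nearest to another genotype, 10 of 11 were nearest to each other's genotype (exact binomial p = 0.00013). The lowest share was 66.7% at day 2, against 33.3% by chance. Libraries of 1 line are not independent, and libraries nearest to each other were both counted, so this p overstates the evidence. The pattern fits a shared origin as well as a small effect of Cdc14a loss. For Cdc14b KO with Cdc14ab KO the count was 8 of 11 (exact binomial p = 0.0088, with the same limits). It was 1 of 4 (25%) at day 0 and all at days 2 and 7. A shared origin of this pair therefore stays open, and an effect of Cdc14b that appears with differentiation was not tested.

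The record of wild-type clone 3 at day 7 holds a description as undifferentiated. Its median signed change of 1.73 lies among the other day 7 libraries, so an undifferentiated sample is unlikely.

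In the day 2 interaction of Cdc14ab KO the list medians were 1.17 for naive pluripotency, -1.16 for neuron (-1.18 with bounded genes) and 0.30 for mitosis. In the day 7 interaction of Cdc14ab KO they were, with bounded values in brackets, -1.79 for neural progenitor, -3.12 for neuron (-3.17), 1.82 for trophectoderm, -1.05 for Hox genes (-1.41), -0.89 for bivalent developmental regulators and -0.72 for imprinted genes. In the Cdc14a KO interaction naive pluripotency had 0.76. In the Cdc14b KO interaction the medians were 0.72 for naive pluripotency (0.58 with bounded genes), 0.23 for general pluripotency, -1.14 for neural progenitor (-1.25), -1.97 for neuron (-2.49), 0.87 for trophectoderm (0.79), -0.85 for imprinted genes, 0.34 for cholesterol synthesis and -0.79 for mitochondrially encoded transcripts. With an estimated correlation, of all these lists only the imprinted genes of the Cdc14b KO interaction kept an adjusted p under 0.05 (0.01).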

How the results depend on the processing

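Of the tests printed here, the fit without the libraries rich in Gm42418 reads, the crossed block and the ranges of the correlations of knockout effects were chosen after the results were seen. The others were chosen before.

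Groups of 2 clones leave each value resting on few libraries, and with 2 clones per genotype an effect of genotype is hard to separate from differences between lines. The cause of each difference below was not tested unless the setting itself removed genes or libraries.

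With DESeq2 on recovered reads the counts were 268 (wild type day 2), 1854 (wild type day 7), 802 (Cdc14ab KO day 2), 2309 (Cdc14a KO day 7), and 1247 (Cdc14b KO day 7). They were 447 and 650 (Cdc14ab KO against wild type at days 0 and 7), 2, 7 and 167 (Cdc14b KO against wild type at days 0, 2 and 7), 957 (Cdc14ab KO interaction at day 7), and 30 and 115 (Cdc14ab KO against the single knockouts at days 0 and 7). With edgeR they were 29 for wild type day 2 and 24 for Cdc14ab KO day 2. With a pseudocount of 5 they were 85 for the day 7 interaction and 8 for Cdc14b KO against wild type at day 7. With a filter of 50 normalized counts, which tests fewer genes, they were 62 for that interaction and 163 for Cdc14ab KO against wild type at day 7. With clone as a random effect they were 80 for Cdc14ab KO day 2 and 126 for the day 7 interaction.

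With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, the counts were 4 (wild type day 2), 2189 (wild type day 7), 0 (Cdc14ab KO day 2), 52 (Cdc14ab KO day 7) and 2416 (Cdc14a KO day 7). They were 0 (Cdc14ab KO against wild type at day 7), 1 (Cdc14b KO against wild type at day 0) and 0 (day 7 interaction). Without the 3 libraries rich in Gm42418 reads they were 35 (wild type day 2), 1 (Cdc14ab KO day 2), 304 (Cdc14ab KO day 7), 207 (Cdc14b KO day 7), 114 (Cdc14ab KO against wild type at day 7) and 0 (day 7 interaction). TMM factors moved the median gene by at most 0.033.

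For changes over days and interactions, the replicate block fitted a clone offset within each genotype. It gave 112 for wild type day 2, 172 for Cdc14ab KO day 2, 267 for the day 7 interaction, and 2 lists in place of 1 for the Cdc14a KO interaction. Between genotypes the block fitted 1 clone-number offset over all genotypes and days, which does not remove sharing particular to a day. That fit gave 376 for Cdc14ab KO against wild type at day 7. It gave 1 for Cdc14b KO against wild type at day 7 and 1 for Cdc14ab KO against the single knockouts at day 7. Between genotypes the labels share only the number, although deviations of same-numbered clones on the same day correlated at -0.134 to 0.628, and at 0.231 to 0.541 at day 7. There the lists called went from 11 to 12 and 7 to 8 (Cdc14ab KO against wild type at day 7 and against the single knockouts at day 2), 8 to 6 (Cdc14a KO at day 7) and 12 to 13 (Cdc14b KO at day 7). Beyond these and the lists printed with the paired comparisons, the block changed no other call of a count by more than 1.5 times. Exchanging the wild-type day 2 numbers, where deviations correlated at -0.115, gave 130.

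With an estimated inter-gene correlation the lists called went from 10 to 3 (wild type day 2), 17 to 3 (wild type day 7), 9 to 0 (Cdc14ab KO day 2), 13 to 0 (Cdc14ab KO day 7), 20 to 2 (Cdc14a KO day 7), and 15 to 0 (Cdc14b KO day 7). Against wild type they went from 10 to 0 and 11 to 0 (Cdc14ab KO at days 2 and 7), 1 to 0 and 8 to 0 (Cdc14a KO at days 2 and 7), 5 to 0, 12 to 0 and 12 to 2 (Cdc14b KO at days 0, 2 and 7). For interactions they went from 3 to 0 and 6 to 0 (Cdc14ab KO at days 2 and 7), 1 to 0 (Cdc14a KO) and 8 to 1 (Cdc14b KO), and 7 to 0 and 9 to 0 (Cdc14ab KO against the single knockouts at days 2 and 7).

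Leaving out 1 library at a time, the counts ranged from 7 to 69 (wild type day 2), 160 to 665 (wild type day 7), 0 to 2442 (Cdc14ab KO day 2), 401 to 4299 (Cdc14ab KO day 7), 297 to 805 (Cdc14a KO day 7), and 178 to 345 (Cdc14b KO day 7). They ranged from 0 to 2228 and 0 to 517 (Cdc14ab KO against wild type at days 0 and 7), 0 to 65 (Cdc14b KO against wild type at day 7). For the others they were 0 to 888 and 0 to 1971 (Cdc14ab KO interactions at days 2 and 7), 0 to 4 (Cdc14b KO interaction), and 0 to 1699 and 0 to 204 (Cdc14ab KO against the single knockouts at days 0 and 7). Each omission leaves fewer libraries, and the lone clone is assumed to vary like other groups. The correlations of knockout effects ranged at day 0 from 0.33 to 0.68 (Cdc14ab with Cdc14a), 0.39 to 0.73 (Cdc14ab with Cdc14b) and 0.26 to 0.68 (Cdc14a with Cdc14b). At day 2 they ranged from 0 to 0.63, 0.47 to 0.88 and 0.02 to 0.61, and at day 7 from 0.22 to 0.66, 0.51 to 0.82 and 0.05 to 0.56. The difference in extent ranged from -0.49 to -0.08 at day 2 and from -0.2 to 0.09 at day 7. A reversed sign was counted only for named genes whose value with all libraries was called or lay over 1 SE from 0. Signs reversed for Cdc14a, Cdc14ab KO versus wild type at day 2 (-2.13 without wild-type day 2 clone 3 to 0.21 without clone 1). So they did for Utf1 in Cdc14a KO at day 0 (-0.96 without Cdc14a KO day 0 clone 3 to 0.01 without clone 1), and Cdc14b in Cdc14b KO at day 2 (-0.99 without Cdc14b KO day 2 clone 3, 0.02 without wild-type day 2 clone 3 and 0.14 without Cdc14b KO day 2 clone 1).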

Other observations

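Of the tests cited here, the one of a second active X chromosome was chosen before the results were seen, and that of partner genotypes was chosen after.

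Rian and Mirg, noncoding RNAs of the imprinted Dlk1-Dio3 region, fell in Cdc14ab KO by day 7, Rian from 3990 ± 607 to 429 ± 37.4 and Mirg from 2230 ± 1190 to 169 ± 29.9, while wild type went from 1260 ± 478 to 1430 ± 35 and from 576 ± 49.9 to 384 ± 46.3. Silencing of this region differs between stem cell lines, and the difference may belong to the lines and not to the phosphatases. At day 0 only 25% of the Cdc14b KO and Cdc14ab KO libraries nearest to another genotype were nearest to their partner, which leaves a shared origin of those lines open, and lines of independent origin are needed to tell these apart.

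Zscan4c and Tmem92, genes of the 2-cell-like state, rose by day 7 in all 4 genotypes, with Zscan4c at 44.9 ± 28.5 in wild type and 82.9 ± 2.68 in Cdc14b KO. Stra8 rose by day 7 to 3760 ± 1500 in wild type, 4560 ± 1110 in Cdc14b KO and 4260 ± 3820 in Cdc14ab KO, next to other retinoic acid targets. No called difference from wild type at day 7 was found for Zscan4c, Tmem92 or Stra8 in any knockout by limma.

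Krt8 was higher at day 7 than at day 0 in both clones of every genotype, and its day 7 difference between Cdc14ab KO and wild type was not called. As log2(normalized count + 1) it was at 10.81 and 13.25 in Cdc14ab KO clones 1 and 3 at day 7. It was at 10.98 and 11.45 in those of Cdc14a KO. Tead4 stood above wild type in Cdc14ab KO. Both genes were higher in clone 3 of Cdc14ab KO than in clone 1. Whether the Cdc14ab KO cells were on an extraembryonic path was not tested, and single-cell or protein data for KRT8 and MAP2 in further clones would show it.

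A second active X chromosome, if the Cdc14ab KO lines held one, could by itself delay exit from the naive state, as is known for XX stem cells. The X-linked minus autosomal difference from wild type, 0.23 at day 0 and -0.11 at day 7, leaves its presence open, and Y-linked RNA was also low in wild-type and Cdc14a KO clone 3. Sex-matched lines or rescue by re-expressed Cdc14b would test it.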
